A study of Mus musculus with 15 samples.

How the data were processed

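The data were RNA sequencing values of tibialis anterior muscle from 15 female mice, each sample a separate library. Per the labels, tissue was homogenised in Trizol, libraries were made with a stranded mRNA kit (TruSeq) and sequenced on an Illumina NovaSeq instrument. The deposited table held TPM, transcript abundance scaled to a fixed sum per library, for 47643 gene symbols, computed by the authors against the mouse genome build mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation and any filter are not given in the sources used here. Each column of the deposited TPM summed to 1000000, so the values keep no sequencing depth, and no counting interval or detection limit could be given.

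Samples were grouped by the treatment in the labels into control (4 libraries), lisinopril (3), melanoma (4) and melanoma plus lisinopril (4). The groups, comparisons, gene lists, tests and most alternatives were fixed before the data were examined. Of 21659 symbols with any value above 0, 11923 had at least 1 TPM in at least 3 of the 15 libraries and were kept. The values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 4 group means over all libraries, 11 residual degrees of freedom and eBayes with trend. The prior degrees of freedom came to 3.80. The 6 contrasts were melanoma against control, lisinopril against control, melanoma plus lisinopril against melanoma, melanoma plus lisinopril against lisinopril, their interaction, and the average of the tumour effect over both drug arms. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and 0.05 was the threshold. Errors of log2 fold changes are standard errors from limma, and errors of TPM are standard deviations.

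Named genes followed a rule. For melanoma against control and melanoma plus lisinopril against melanoma it took up to 10 genes in each direction with the largest change among those past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between the groups compared. For other contrasts it took up to 5 in each direction under the same conditions. It also took up to 4 members past the threshold from each list, and a panel of 18 genes whatever their result. Separation of the groups is thus no separate evidence for genes chosen by size of change. The text names part of the genes this rule gave. Genes of Y-linked and lymphocyte checks outside it are identified where they appear.

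43 gene lists covering muscle, metabolism, inflammation, stress and cell types were tested with limma's camera at a preset correlation of 0.01, adjusted over the 41 lists with at least 3 kept genes, and again with an estimated correlation. List medians are given relative to the median of all kept genes in the same contrast. After the data were seen, an exact permutation test of list levels was added, in which a list's level is the mean of its genes minus the mean of all kept genes of that library, with 6435 relabellings of tumour-bearing and tumour-free libraries, or 3003 without control 2. For a list, the number of tumour-bearing libraries in its direction counts those on that side of the tumour-free mean of this level. It does not mean that they lay beyond every tumour-free library, as it does for single genes. The tumour response score of a library is the mean log2(TPM + 1) of the genes higher in the average tumour effect minus that of the genes lower in it. It was compared between groups by exact permutation (70 or 35 relabellings), with 95% intervals from inverted permutation tests. For the interaction of the score all 2450 relabellings within tumour status were used, where a smaller set had been planned, because mirrored relabellings give different values of a signed difference.

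The fit was tested on simulated data with known changes, and the share recovered is given with each contrast. In simulated data without changes limma made 0 calls in each contrast. The simulated noise was independent between genes and libraries, with the same spread of a gene in every library. It holds no correlation between genes and no outlying library, so neither result gives the error or recovery in the real data. Alternatives were a pseudocount of 0.1, no filter, a stricter filter (mean of at least 5 TPM), median-ratio rescaling, quantile normalization, eBayes without trend, sample quality weights, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library. TPM recomputed without the mitochondrial genome, leaving out control 2 and melanoma 2 together, and the latter with median-ratio rescaling were added after the data were seen. An analysis meant for read counts was not run because the table holds TPM. Gene positions came from the GENCODE annotation of the same build, in which 94.7% of the symbols (45134) were found. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The lists of natural killer cell genes and of keratinocyte genes had fewer than 3 kept genes and were not tested, and no sample was left out of the comparisons.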

Results

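The transcriptome of the tibialis anterior, a muscle of the lower hind limb, was measured in 15 female mice, 49 days after a melanoma that induces cachexia (wasting of muscle and fat) was implanted or a mock injection was given, per the series design text. The protocol label also mentions 3 weeks, for another tumour model, so the time rests on the design text alone. Whether the age of 7 weeks is that at implantation or at collection is not stated. Mice of each kind received lisinopril, an inhibitor of angiotensin-converting enzyme, or a mock treatment. The groups were 4 control mice with neither tumour nor drug, 3 mice with lisinopril alone, 4 with melanoma and 4 with melanoma and lisinopril. Sequencing depth is unknown, since TPM keep no totals. Between 10530 and 12363 genes reached 1 TPM per library. Xist, expressed from the inactive X chromosome, lay between 9.63 and 48.4 TPM in the 15 libraries, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together reached at most 0.00984 TPM. The authors' counting of reads shared between close relatives is not given, so values of the haemoglobins, ribosomal proteins, Serpina3n, C4b and Ly6c1 are uncertain to that extent.

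Mitochondrially encoded transcripts made up 44.3 ± 5.68% of TPM in control (SD, n = 4), 44.9 ± 2.05% with lisinopril (n = 3), 39.3 ± 5.79% with melanoma (n = 4) and 38.9 ± 7.00% with melanoma and lisinopril (n = 4). The first principal component held 42.4% of the variance and the second 16.8%. Control 2 and melanoma 2 stood apart, with mean correlations to their own group of 0.937 and 0.938, against at least 0.965 for every other library. Control 2 held 23878 TPM of haemoglobin, the oxygen carrier of red blood cells, while the other 14 libraries held at most 4197 TPM. Igkc, the immunoglobulin kappa constant region, reached 80.1 TPM in control 2 and 61.2 TPM in lisinopril 1, and at most 4.08 TPM in every other library. Melanoma 2 held 986 TPM of Fbxo32 and 1974 TPM of Trim63, ubiquitin ligases of muscle atrophy.

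Melanoma against control asks what the tumour changed in muscle without the drug. Acute phase and complement transcripts were higher in the tumour-bearing muscles. Serpina3n, a secreted inhibitor of serine proteases, had 4.89 ± 4.16 TPM in control (SD, n = 4) and 288 ± 402 TPM with melanoma (n = 4), 28.8-fold higher by the group means of log2(TPM + 1) (log2 fold change 4.85 ± 0.93, adjusted p = 0.0315). The complement components C3 (2.95 ± 0.37) and C4b (2.92 ± 0.38), the lipopolysaccharide-binding protein Lbp (2.08 ± 0.32), the oncostatin M receptor Osmr (1.63 ± 0.28) and Stat3 (1.34 ± 0.24), the transcription factor that transmits signals of interleukin-6 type cytokines, rose as well, in log2 units ± SE. Each of C3, C4b, Lbp and Stat3 was above every control library in 4 of 4 melanoma libraries. For genes named by size of change, such as C3, C4b and Lbp, this was a condition of selection. The immunoglobulin heavy chain gene Ighm fell from 63.2 ± 18.7 to 4.73 ± 2.84 TPM (log2 fold change -3.57 ± 0.60, adjusted p = 0.0188). Fabp3, the fatty acid-binding protein of heart and muscle, fell from 1028 ± 242 to 399 ± 28.8 TPM (log2 fold change -1.34 ± 0.21, adjusted p = 0.0138).

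In all, 55 genes rose and 22 fell among 11923, and 2209 had an unadjusted p below 0.05. Of these calls, 71.4% were higher, against 52.6% without the mitochondrial genome, 60.7% with median-ratio rescaling and 64.1% with quantile normalization. Further genes that rose were Prg4 (2.42), which encodes lubricin, the lipid carrier Apod (2.21), the haptoglobin-haemoglobin scavenger receptor Cd163 (1.97), the chemokine Cxcl14 (1.69), the interleukin-1 receptor Il1r1 (0.97), and Lpin1 (1.33), a phosphatidate phosphatase. Further genes that fell were Ccnd1 (-1.76), which encodes cyclin D1, the natriuretic peptide clearance receptor Npr3 (-1.51), Oxct1 (-1.25), which starts ketone body use, Fndc5 (-1.16), the precursor of irisin, Slc25a20 (-0.62), the carnitine-acylcarnitine carrier of mitochondria, and Cyfip2 (-2.75). Other named genes past the threshold were Sned1 (2.24), Map3k6 (2.13), Atp9a (2.04), Fcna (2.01) and Steap4 (1.03), which rose, and Rmdn1 (-0.94) and Msrb2 (-0.78), which fell. Serpina3n (chromosome 12, 104406729 to 104414329) and Ighm (chromosome 12, 113418558 to 113422730) lie on the mm10 build at the positions given, as does Fabp3 (chromosome 4, 130308595 to 130315463). The atrophy ligases Trim63 (log2 fold change 1.28 ± 0.59, adjusted p = 0.262) and Fbxo32 (log2 fold change 1.22 ± 0.66, adjusted p = 0.320) did not pass, nor did Ace (log2 fold change 1.62 ± 0.41, adjusted p = 0.0810), the target of lisinopril.

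By camera, 10 of 41 fixed lists were higher and 12 lower relative to all genes, whose median log2 fold change was 0.10. Fatty acid oxidation and PPAR targets fell (median -0.45 relative to all genes, adjusted p = 7.60e-10, and adjusted p = 0.0163 with an estimated correlation), the only list of this contrast past the threshold under both correlations. In it 2 of 32 genes fell over all genes tested and 15 fell adjusted over the list alone. Acute phase genes rose by camera (median 1.08 relative to all genes, adjusted p = 6.19e-10, and adjusted p = 0.505 with an estimated correlation), with 4 of 26 members higher and 17 higher adjusted over the list alone. Neutrophil markers rose by camera (median 1.63 relative to all genes, adjusted p = 1.53e-07, and adjusted p = 0.409 with an estimated correlation), with 0 of 9 members higher and 9 adjusted over the list alone. Atrophy genes rose by camera (median 0.66 relative to all genes, adjusted p = 3.09e-06, and adjusted p = 0.684 with an estimated correlation), with 0 of 35 higher and 7 adjusted over the list alone.

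The count of 77 moved with single libraries, to 22 without control 1, 590 without control 2, 17 without control 3, 22 without control 4, 40 without lisinopril 1, 37 without lisinopril 2, 39 without lisinopril 3, 31 without melanoma 1, 19 without melanoma 2, 36 without melanoma 3 and 50 without melanoma plus lisinopril 1. It was 40 with no filter, 30 with the stricter filter, 5 with only the 2 groups compared, 120 with the replicate block, 137 without the mitochondrial genome, 163 with median-ratio rescaling, 359 with quantile normalization, 1710 with sample quality weights and 257 without control 2 and melanoma 2. Of the 28 named genes called here, 7 were still called without control 3, the fewest, and 12 with no filter. In simulated data of this contrast, 79.1% of genes changed by 1 log2 unit were recovered.

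Melanoma plus lisinopril against lisinopril asks for the tumour effect in mice given the drug. The acute phase genes Serpina3n and Lcn2, the metallothioneins Mt1 and Mt2, which bind zinc and copper, and Fkbp5, a co-chaperone of the glucocorticoid receptor, were the named genes with the largest rises. Serpina3n had 1.42 ± 0.290 TPM with lisinopril (SD, n = 3) and 170.1 ± 201 TPM with melanoma and lisinopril (n = 4; log2 fold change 5.28 ± 1.00, adjusted p = 0.0254). Lcn2, lipocalin 2, which binds bacterial siderophores, had 0.742 ± 0.510 and 85.8 ± 80.6 TPM (log2 fold change 4.78 ± 1.07, adjusted p = 0.0447), and Mt2 had 155 ± 93.2 and 2520.3 ± 1601 TPM (log2 fold change 3.89 ± 0.69, adjusted p = 0.0219). Fkbp5 rose by 3.69 ± 0.67 and Mt1 by 3.32 ± 0.65. Ighm fell from 93.1 ± 69.8 to 7.60 ± 8.48 TPM (log2 fold change -3.59 ± 0.65, adjusted p = 0.0237).

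Here 160 genes rose and 17 fell, with 2781 at an unadjusted p below 0.05. In this contrast 90.4% of the called genes were higher, against 82.6% without the mitochondrial genome, 70.3% with median-ratio rescaling and 72.4% with quantile normalization. Stat3 (1.96 ± 0.25), Osmr (1.82 ± 0.31) and haptoglobin, Hp (2.49 ± 0.52), of the acute phase list rose, as did the glucocorticoid-responsive transcription factor Zbtb16 (1.99). The clock-linked repressor Nfil3 (2.53), the nuclear receptor Nr4a3 (2.47), the collagen cross-linking enzyme Lox (2.37), the fatty acid transporter Cd36 (1.05) and the lysosomal membrane protein Lamp2 (1.11) rose too. Ace, whose enzyme lisinopril inhibits, rose from 7.91 ± 1.27 to 34.6 ± 8.48 TPM (log2 fold change 1.98 ± 0.44, adjusted p = 0.0447). Angptl2 (-1.67), Inha (-1.47), Iqcg (-1.03) and Dcakd (-0.99) fell. Camera put 7 lists higher and 10 lower, none of them past the threshold with an estimated correlation. Acute phase genes were 9 of 26 higher over all genes and 18 adjusted over the list alone (median 1.15 relative to all genes, adjusted p = 2.11e-08, and adjusted p = 0.654 with an estimated correlation). Atrophy genes were 2 of 35 higher and 12 adjusted over the list alone (median 0.80 relative to all genes, adjusted p = 1.69e-05, and adjusted p = 0.744 with an estimated correlation). Extracellular matrix genes were lower in the test (median -0.11 relative to all genes, adjusted p = 0.0296, and adjusted p = 0.919 with an estimated correlation), while their unadjusted median change was 0.12 and their mean change 0.050. That call ended, with the median at -0.13 with median-ratio rescaling, -0.087 with quantile normalization, -0.12 without the mitochondrial genome, -0.090 with the stricter filter and -0.049 with the replicate block. It also ended with no filter, where the median turned to 0.082. Without single libraries it ended with the median above 0, for lisinopril 2 (0.15) or melanoma plus lisinopril 4 (0.0058).

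The count of 177 was 94 without control 1, 581 without control 2, 266 without control 3, 92 without control 4, 5 without lisinopril 1, 25 without lisinopril 2, 10 without lisinopril 3, 98 without melanoma 1, 681 without melanoma 2, 105 without melanoma 3, 8 without melanoma plus lisinopril 1, 20 without melanoma plus lisinopril 2, 385 without melanoma plus lisinopril 3 and 28 without melanoma plus lisinopril 4. It was 14 with no filter, 356 with the replicate block, 876 with only the 2 groups compared, 2303 with sample quality weights and 1914 without control 2 and melanoma 2. Of the 33 named genes called here, only Stat3 was still called with no filter, without lisinopril 1, without lisinopril 3, without melanoma plus lisinopril 1 and without melanoma plus lisinopril 2. In simulated data 56.7% of genes changed by 1 log2 unit were recovered.

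The average of both tumour effects uses all 15 libraries, 8 with tumour and 7 without, and asks what the tumour changed whether or not the drug was given. It called 2141 genes, 1730 higher and 411 lower, with 4526 at an unadjusted p below 0.05. The share of higher calls depended on scaling: 80.8% of the called genes were higher, against 59.7% without the mitochondrial genome, 46.7% with median-ratio rescaling and 50.0% with quantile normalization. Serpina3n rose 33.5-fold by the group means of log2(TPM + 1) (log2 fold change 5.06 ± 0.68, adjusted p = 9.75e-04). It lay above every tumour-free library in 8 of 8 tumour-bearing libraries, as did C3 (2.86 ± 0.27), C4b (3.05 ± 0.28), Mt1 (2.93 ± 0.44), Mt2 (3.35 ± 0.47) and Stat3 (1.65 ± 0.17). Lcn2 rose by 4.56 ± 0.73 and was above every tumour-free library in 7 of 8. Ighm (-3.58 ± 0.44), the muscle methyltransferase gene Mettl21e (-1.72 ± 0.37), Lrtm1 (-1.83 ± 0.32), Trim7 (-1.28 ± 0.34) and Ptges3l (-1.21 ± 0.23) fell, each below every tumour-free library in 8 of 8. For genes named by size of change, rising or falling, 8 of 8 was a condition of selection and not an outcome. Myoglobin, Mb (-1.15 ± 0.27), and cardiac alpha-actin, Actc1 (-3.14 ± 0.55), which the developing muscle also makes, fell as well. The median log2 fold change of all genes was 0.17. It was -0.0039 with median-ratio rescaling and 0.00073 with quantile normalization, and list changes are relative to it.

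**Figure D1:**
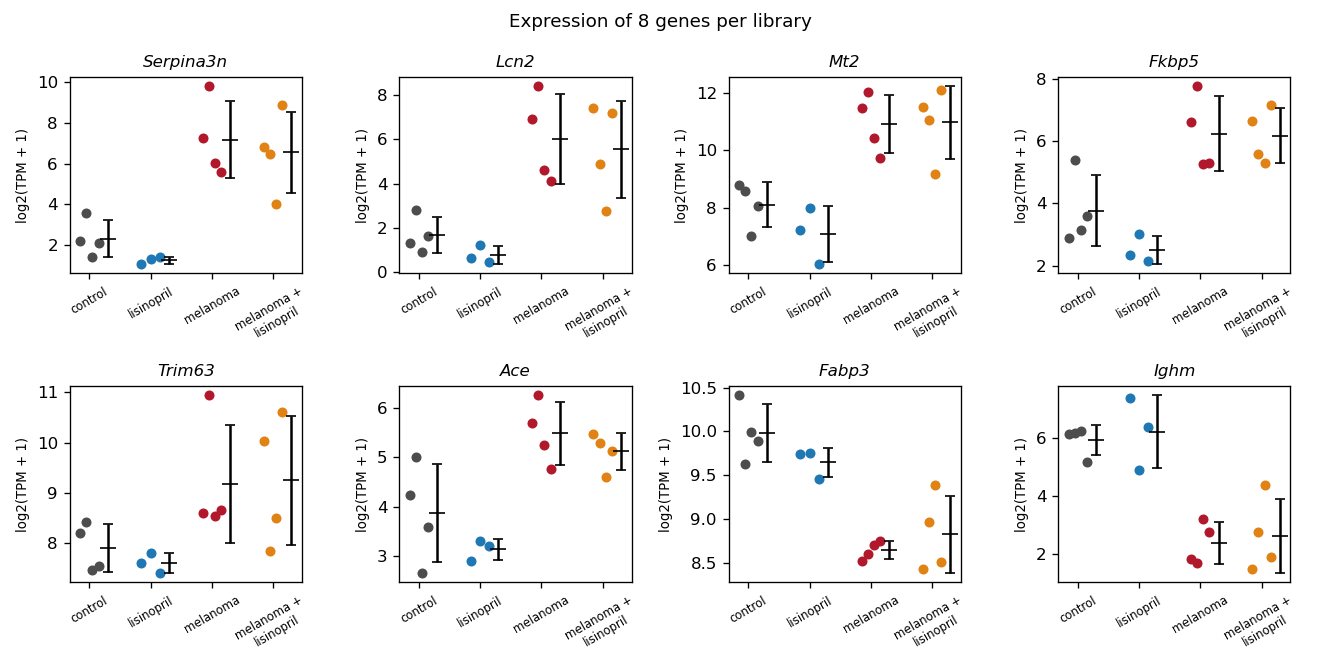
Levels of 8 genes as log2(TPM + 1) in each library of the 4 groups, with the group mean and SD beside the points. Serpina3n and Mt2 lay above every tumour-free library in 8 of 8 tumour-bearing libraries, and Fabp3 and Ighm below every one in 8 of 8.

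Inflammation-related lists moved apart. Acute phase genes rose by camera, 19 of 26 members over all genes and 25 adjusted over the list alone (median 1.20 relative to all genes, adjusted p = 2.55e-09, and adjusted p = 0.447 with an estimated correlation; exact permutation p = 4.66e-04, adjusted 0.00319), with Stat3, Osmr (1.73) and Steap4 (0.99) among them. Neutrophil markers rose, 9 of 9 over all genes and 9 adjusted over the list alone (median 1.29 relative to all genes, adjusted p = 1.07e-05, and adjusted p = 0.447 with an estimated correlation; exact permutation p = 4.66e-04, adjusted 0.00319), including Cxcr2 (1.43), a chemokine receptor, Il1r2 (1.46), the decoy receptor of interleukin-1, and Retnlg (2.27). Interferon-stimulated genes fell by camera, 3 of 27 over all genes and 2 adjusted over the list alone (median -0.80 relative to all genes, adjusted p = 7.76e-07, and adjusted p = 0.677 with an estimated correlation; exact permutation p = 0.0117, adjusted 0.0392). Those past the threshold were Gbp3 (-1.17), a guanylate-binding protein, and Tap1 (-0.83) and Psmb9 (-0.76), which serve antigen presentation. In control 2, which stood apart, the mean level of the interferon list was 5.10 in log2(TPM + 1), against 1.48 to 1.90 in the other tumour-free libraries and 1.22 to 1.94 in the tumour-bearing ones. Without control 2 the median of the list was -0.35, still called by camera, and the list did not pass the permutation test (exact p = 0.0383, adjusted 0.0785), with 6 of 8 tumour-bearing libraries below the tumour-free mean. Control 2 also held the highest level of Tap1 and Psmb9 among the controls (12.6 and 6.66 TPM). T and B lymphocyte genes fell by camera with 1 of 3 kept members, Ighm, and 2 adjusted over the list alone (median -2.30 relative to all genes, adjusted p = 9.89e-04, and adjusted p = 0.316 with an estimated correlation; exact permutation p = 1.55e-04, adjusted 0.00319). The kept members include both immunoglobulin genes, Ighm and Igkc. The T cell gene Cd3e stayed below the filter, at most 0.439 TPM (control 2), so a fall of T cells was not shown. With control 2 included, each list of this paragraph lay on its side of the tumour-free mean in 8 of 8 tumour-bearing libraries. The interferon and lymphocyte calls ended with median-ratio rescaling when control 2 and melanoma 2 were left out (medians -0.26 and -1.63).

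Genes of muscle wasting and glucocorticoid action rose. Of the atrophy genes 18 of 35 rose, and 24 adjusted over the list alone (median 0.68 relative to all genes, adjusted p = 4.06e-06, and adjusted p = 0.677 with an estimated correlation; exact permutation p = 4.66e-04, adjusted 0.00319). Examples were Foxo1 (1.85 ± 0.35), a transcription factor that drives atrophy programmes, Eif4ebp1 (2.40 ± 0.44), a repressor of translation, the cell cycle inhibitor Cdkn1a (1.45 ± 0.37) and the muscle ubiquitin ligase Trim63 (1.47 ± 0.43). Fbxo32 missed the threshold (log2 fold change 1.27 ± 0.48, adjusted p = 0.0732). Glucocorticoid-responsive genes rose by camera, 16 of 27 over all genes and 22 adjusted over the list alone (median 0.82 relative to all genes, adjusted p = 4.06e-06, and adjusted p = 0.666 with an estimated correlation; exact permutation p = 3.11e-04, adjusted 0.00319), among them Fkbp5 (3.08 ± 0.45) and Lpin1 (1.21 ± 0.16). The list shares Trim63, Fbxo32, Cdkn1a, Foxo1, Mt1 and Mt2 with the atrophy list, among others. Autophagy and lysosome genes rose by camera, 11 of 42 over all genes and 22 adjusted over the list alone (median 0.18 relative to all genes, adjusted p = 0.00344, and adjusted p = 0.870 with an estimated correlation; exact permutation p = 0.00109, adjusted 0.00557), with Optn (0.96), Map1lc3b (1.14) and Sqstm1 (0.96) of the autophagosome and Lamp2 (0.89) of the lysosome. Cytoplasmic ribosomal proteins rose by camera, 21 of 56 over all genes and 48 adjusted over the list alone (median 0.35 relative to all genes, adjusted p = 1.10e-07, and adjusted p = 0.828 with an estimated correlation; exact permutation p = 0.0112, adjusted 0.0392). Genes of the unfolded protein response had 3 of 20 higher and 9 adjusted over the list alone (median 0.35 relative to all genes, adjusted p = 0.00956, and adjusted p = 0.870 with an estimated correlation; exact permutation p = 0.0214, adjusted 0.0517), with Xbp1 (0.95), its transcription factor. The unfolded protein response was above the tumour-free mean in 7 of 8 tumour-bearing libraries and the other lists of this paragraph in 8 of 8.

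Genes of mitochondrial energy metabolism fell relative to all genes. In oxidative phosphorylation, 7 of 36 genes of complex I fell, and 8 adjusted over the list alone (median -0.34 relative to all genes, adjusted p = 6.94e-11, and adjusted p = 0.447 with an estimated correlation; exact permutation p = 0.0193, adjusted 0.0494). In complexes II to V 10 of 36 fell, and 16 adjusted over the list alone (median -0.36 relative to all genes, adjusted p = 1.10e-12, and adjusted p = 0.374 with an estimated correlation; exact permutation p = 0.0124, adjusted 0.0392). Ndufs8 (-0.45 ± 0.10) and Ndufs1 (-0.54 ± 0.14) of complex I, Cox7a1 (-0.65 ± 0.17) of cytochrome c oxidase and Atp5g3 (-0.45 ± 0.11) of ATP synthase were among them. Of the tricarboxylic acid cycle 6 of 22 fell, and 10 adjusted over the list alone (median -0.41 relative to all genes, adjusted p = 2.55e-09, and adjusted p = 0.374 with an estimated correlation; exact permutation p = 0.0113, adjusted 0.0392), including the malate dehydrogenases Mdh1 (-0.66) and Mdh2 (-0.32). Of fatty acid oxidation and PPAR targets 11 of 32 fell, and 14 adjusted over the list alone (median -0.36 relative to all genes, adjusted p = 2.16e-05, and adjusted p = 0.224 with an estimated correlation; exact permutation p = 0.0179, adjusted 0.0488), such as Fabp3 (-1.08 ± 0.15) and the short-chain dehydrogenase Acads (-0.70), while Cd36 (0.71 ± 0.16) rose. Members of that list went both ways, with an unadjusted mean of -0.048 against an unadjusted median of -0.19. The 13 mitochondrially encoded mRNAs fell by camera with 0 single genes past the threshold over all genes and 0 adjusted over the list alone (median -0.35 relative to all genes, adjusted p = 8.43e-05, and adjusted p = 0.677 with an estimated correlation; exact permutation p = 0.0657, adjusted 0.142). The first 4 of these lists passed the exact permutation test after adjustment and the mitochondrially encoded mRNAs did not, and their camera call ended with quantile normalization (median -0.071). Fatty acid oxidation genes and mitochondrially encoded mRNAs were below the tumour-free mean in 7 of 8 tumour-bearing libraries, the other lists of this paragraph in 8 of 8.

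**Figure D2:**
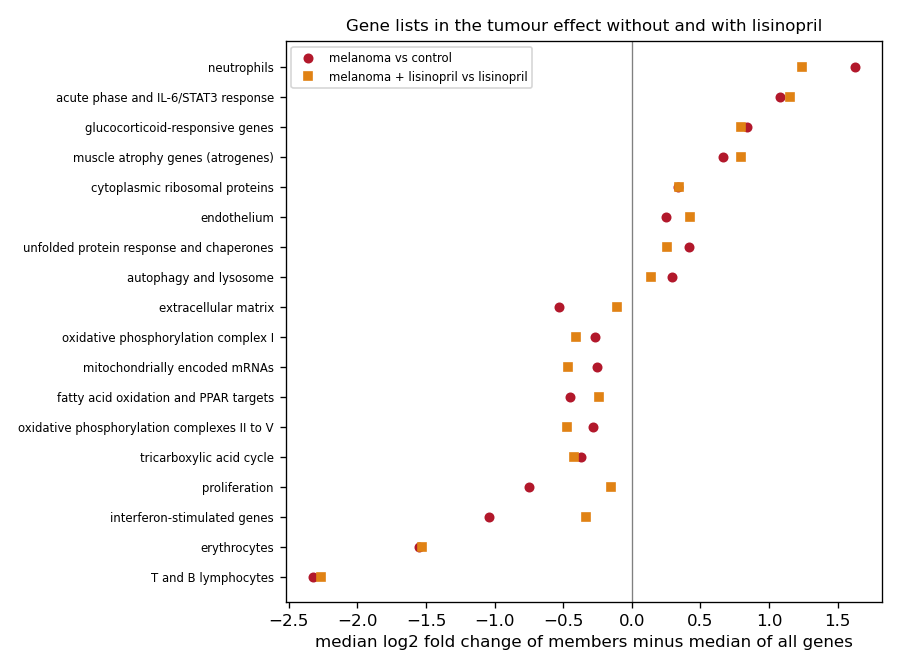
Median log2 fold change of each list called by camera in the average tumour effect, minus the median of all genes, in mice without (circles) and with lisinopril (squares). Acute phase genes lay at 1.08 and 1.15, and fatty acid oxidation genes at -0.45 and -0.24.

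Other lists called by camera were endothelium, with 9 of 21 members higher and 13 adjusted over the list alone (median 0.35 relative to all genes, adjusted p = 0.0102, and adjusted p = 0.828 with an estimated correlation; exact permutation p = 0.0166, adjusted 0.0487), and extracellular matrix, with 2 of 43 lower and 1 adjusted over the list alone (median -0.29 relative to all genes, adjusted p = 3.85e-04, and adjusted p = 0.828 with an estimated correlation; exact permutation p = 0.155, adjusted 0.276). Members that rose included Lyve1 (1.59) of lymphatic vessels, which the macrophage list also holds. Flt1 (0.79), a receptor of vascular endothelial growth factor, rose too, while Kdr (-0.85), another such receptor, fell. In the matrix list the basement membrane collagen Col15a1 (-0.77) and tenascin C, Tnc (-0.87), fell, while Lox (1.88) and decorin, Dcn (0.87), rose, and the main fibrillar collagens Col1a1 (log2 fold change -0.96 ± 0.59, adjusted p = 0.240) and Col3a1 (log2 fold change -1.58 ± 0.67, adjusted p = 0.101) did not pass. Erythrocyte genes (median -1.53 relative to all genes, adjusted p = 0.00767, and adjusted p = 0.666 with an estimated correlation; exact permutation p = 0.107, adjusted 0.210) and proliferation genes (median -0.51 relative to all genes, adjusted p = 0.0259, and adjusted p = 0.677 with an estimated correlation; exact permutation p = 1.55e-04, adjusted 0.00319) were lower by camera, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. Both calls ended with median-ratio rescaling (medians -1.57 and -0.48) and quantile normalization (-1.56 and -0.50), where the medians moved little. They also ended without control 2 and melanoma 2, where the medians shrank (-0.71 and -0.22). The proliferation call also ended without control 2 (-0.25) alone. The matrix call ended with median-ratio rescaling without those 2 libraries, while its median stayed at -0.29. The remaining 23 lists had adjusted camera p-values between 0.0691 and 0.995.

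The count of 2141 was 1350 without control 1, 3959 without control 2, 1164 without control 3, 1158 without control 4, 743 without lisinopril 1, 900 without lisinopril 2, 1237 without lisinopril 3, 1383 without melanoma plus lisinopril 1 and 1210 without melanoma plus lisinopril 4. It was 1337 with no filter, 4660 with sample quality weights and 3676 without control 2 and melanoma 2, and in simulated data 76.1% of genes changed by 1 log2 unit were recovered. Of the 115 named genes called here, Serpina3n, Stat3 and Ighm among them, 74 were still called without lisinopril 1, the fewest.

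The tumour effects with and without lisinopril come from separate libraries and were compared across genes. Of the 1730 genes called higher on average, 1729 were higher in both arms, with medians of 0.56 without and 0.72 with the drug. All 411 called lower were lower in both, with medians of -0.65 and -0.51. These genes were chosen on both arms together. Across all 11923 genes, which are not independent replicates, Pearson's r was 0.765 (jackknife SE over libraries 0.129), Spearman's rho 0.754, and 79.7% had the same sign. Called in both arms were 38 genes that rose, among them Serpina3n, Stat3 and Osmr, where independent lists would share 0.738, and 6 that fell, Ighm among them, against 0.0314. The calls of both arms use the same spread estimate of each gene, so they are not independent and these figures are only a reference.

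Melanoma plus lisinopril against melanoma asks what the drug changed in tumour-bearing mice. Genes of fatty acid oxidation and PPAR targets were higher as a group with the drug (median 0.23 relative to all genes, adjusted p = 5.07e-11, and adjusted p = 0.00920 with an estimated correlation), the only list of this contrast past the threshold under both correlations. Over all genes 0 members passed, and 0 adjusted over the list alone. The list was higher in 4 of 4 treated libraries than the mean of the untreated, with an exact permutation p = 0.0857 and an adjusted p = 1 over the lists. Fabp3, the gene of this list with the largest fall in melanoma, had 399 ± 28.8 TPM with melanoma (SD, n = 4) and 469 ± 149 TPM with melanoma and lisinopril (n = 4). The coactivator Ppargc1a, which drives mitochondrial biogenesis, had a log2 fold change of 0.83 ± 0.39 (adjusted p = 1.00).

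By limma, 0 of 11923 genes passed the threshold, and 189 had an unadjusted p below 0.05, where 596 would by chance. Serpina3n (-0.62 ± 0.93), Lcn2 (-0.46 ± 0.99), Trim63 (0.063 ± 0.59), Fbxo32 (-0.35 ± 0.66), Foxo1 (0.19 ± 0.48) and Mt2 (0.059 ± 0.64) had standard errors at least as large as their differences. The target gene Ace differed by -0.37 ± 0.41, the angiotensin precursor Agt by 0.11 ± 0.38, the angiotensin receptor Agtr1a by -0.54 ± 0.22 and myostatin, Mstn, by 0.28 ± 0.43, each with an adjusted p = 1.00. Camera called 11 lists higher and 4 lower. Of these 15 lists, 8 stayed past the threshold and 5 turned without melanoma 2. Without control 2 and melanoma 2 together, 6 stayed past it and 4 turned. Polyamine metabolism was higher (median 0.24 relative to all genes, adjusted p = 2.50e-04, and adjusted p = 0.170 with an estimated correlation; exact permutation p = 0.0286, the smallest that 70 relabellings can give, and adjusted p = 1 over the lists). NF-kB inflammation genes were lower by camera (median -0.63 relative to all genes, adjusted p = 5.39e-08, and adjusted p = 0.635 with an estimated correlation; exact permutation p = 0.143, adjusted 1), with 0 members past the threshold over all genes and 3 adjusted over the list alone. Markers of macrophages and monocytes (median -0.28 relative to all genes, adjusted p = 0.0190, and adjusted p = 0.935 with an estimated correlation) and of neutrophils (median -0.40 relative to all genes, adjusted p = 0.00189, and adjusted p = 0.866 with an estimated correlation) were lower by camera with them. Neither passed the exact permutation test (p = 0.4 and 0.314), and each was lower in 3 of 4 treated libraries than the mean of the untreated. The macrophage call ended without melanoma 3 (-0.12), melanoma 4 (-0.31), melanoma plus lisinopril 1 (-0.23) or melanoma plus lisinopril 4 (-0.11), and the neutrophil call without melanoma 2 (-0.28) or melanoma plus lisinopril 4 (-0.10). In simulated data of this contrast 64.2% of genes changed by 1 log2 unit and 92.4% of those changed by 2 were recovered. Without control 2 and melanoma 2 the changes were 0.25 for Serpina3n, 0.33 for Lcn2 and 0.24 for Fbxo32, all with the sign turned.

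Lisinopril against control asks what the drug changed without a tumour. Camera called gene lists at the preset correlation, 0 of them with an estimated correlation, and 0 single genes passed. The exact permutation test of list levels was not run for this contrast, so the list differences rest on the preset correlation. Fast fibre sarcomere genes were higher by camera (median 0.48 relative to all genes, adjusted p = 9.23e-17, and adjusted p = 0.170 with an estimated correlation), slow fibre genes lower (median -0.85 relative to all genes, adjusted p = 0.00197, and adjusted p = 0.643 with an estimated correlation), extracellular matrix genes lower (median -0.58 relative to all genes, adjusted p = 8.22e-06, and adjusted p = 0.643 with an estimated correlation) and glycolysis genes higher (median 0.44 relative to all genes, adjusted p = 2.46e-12, and adjusted p = 0.170 with an estimated correlation). In each of these lists 0 members passed over all genes and 0 adjusted over the list alone. The fast fibre and glycolysis calls ended with quantile normalization (medians 0.092 and 0.13), and the slow fibre call without control 3 (-0.77) or lisinopril 3 (-0.51). Markers of fibroblasts and fibro-adipogenic progenitors (median -0.28 relative to all genes, adjusted p = 0.00196, and adjusted p = 0.643 with an estimated correlation) and of macrophages and monocytes (median -0.54 relative to all genes, adjusted p = 0.00132, and adjusted p = 0.672 with an estimated correlation) were lower by camera along with the matrix genes. These calls ended without lisinopril 1 (-0.13) for the fibroblast list and without control 2 (-0.23) or lisinopril 3 (-0.38) for the macrophage list. Interferon-stimulated genes were lower (median -0.64 relative to all genes, adjusted p = 0.00100, and adjusted p = 0.810 with an estimated correlation), which rested on control 2: their median relative to all genes was 0.011 without it.

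By limma 0 genes passed, and 461 had an unadjusted p below 0.05 (14 higher and 447 lower), where 596 would by chance. The median of all genes was -0.18. Ace (-0.73 ± 0.44), Col1a1 (-1.10 ± 0.86), Col3a1 (-0.99 ± 0.99), the slow myosin gene Myh7 (-0.50 ± 1.04) and the fast myosin gene Myh4 (0.51 ± 0.34) did not pass. Camera called 11 lists higher and 8 lower, 0 of them with an estimated correlation. Among them the proteasome, the tricarboxylic acid cycle, immediate early genes, polyamine metabolism and mitochondrially encoded mRNAs were higher in the test while their unadjusted mean lay below 0. Quantile normalization ended these calls, with medians of 0.038 for the tricarboxylic acid cycle, 0.075 for immediate early genes and 0.0049 for polyamine metabolism. It turned the proteasome to -0.044 and the mitochondrially encoded mRNAs to -0.050. Single libraries ended them too: the proteasome without control 2 (0.031), control 3 (0.078), lisinopril 1 (0.020) or melanoma 2 (0.077), the tricarboxylic acid cycle without control 2 (0.054), immediate early genes without control 1 (0.12) or control 3 (-0.028), polyamine metabolism without lisinopril 1 (0.046) and the mitochondrially encoded mRNAs without control 2 (0.091) or control 4 (0.16). In simulated data 58.2% of genes changed by 1 log2 unit were recovered. Across genes, the drug effects in tumour-free and tumour-bearing mice had an r of 0.179 and a rho of 0.271, with 67.4% of the same sign.

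The interaction asks whether the tumour effect differed with the drug. Fatty acid oxidation and PPAR targets had a less negative tumour effect with lisinopril (median 0.29 relative to all genes, adjusted p = 4.11e-13, and adjusted p = 0.00447 with an estimated correlation), the only list of this contrast past the threshold under both correlations, with 0 members past the threshold over all genes and 0 adjusted over the list alone. The unadjusted mean of the list was -0.27 for the tumour without lisinopril and 0.44 in the interaction. That unadjusted mean was thus not below 0 with lisinopril, but the median of all genes was 0.23 in that arm. Relative to all genes the list median stayed below 0 with lisinopril, less far than the -0.45 without it, so the fall was smaller and not absent. In melanoma plus lisinopril against lisinopril the list was not called by camera. The unadjusted median of the list was 0.42 in the interaction, 0.17 for the drug in tumour-bearing mice and -0.21 for the drug in tumour-free mice. In the last of these the list was lower by camera (median -0.026 relative to all genes, adjusted p = 0.00755, and adjusted p = 0.269 with an estimated correlation), a call that ended without control 3 (0.047) or lisinopril 3 (0.0061). It also ended with median-ratio rescaling (median -0.0013) and without the mitochondrial genome (-0.012). This contrast and the drug contrast in tumour-bearing mice share all 8 tumour-bearing libraries and are not independent. By limma 0 of 11923 genes passed and 151 had an unadjusted p below 0.05, where 596 would by chance. Serpina3n (0.44 ± 1.36), Trim63 (0.37 ± 0.87), Ace (0.36 ± 0.60) and Pdk4 (0.68 ± 0.75), a kinase that shuts off pyruvate use, did not pass. In simulated data 32.8% of genes changed by 1 log2 unit and 77.3% of those changed by 2 were recovered. Camera called 6 lists higher and 9 lower. Without control 2, 9 of these 15 lists stayed past the threshold and 3 turned. Proteasome subunits (median -0.13 relative to all genes, adjusted p = 0.0466, and adjusted p = 0.997 with an estimated correlation), complexes II to V (median -0.12 relative to all genes, adjusted p = 0.00215, and adjusted p = 0.959 with an estimated correlation) and glycolysis (median -0.20 relative to all genes, adjusted p = 0.0147, and adjusted p = 0.959 with an estimated correlation) were lower in the test while their unadjusted median or mean lay above 0. The proteasome call ended or turned without control 2 (-0.072), control 3 (-0.13), lisinopril 1 (-0.091), melanoma 2 (0.072), melanoma plus lisinopril 2 (-0.045) or melanoma plus lisinopril 3 (-0.092), that of complexes II to V without control 2 (-0.017), melanoma 3 (-0.083), melanoma 4 (-0.066) or melanoma plus lisinopril 4 (-0.064), and that of glycolysis without control 1 (-0.17), control 2 (0.0012), lisinopril 1 (-0.15), melanoma 1 (-0.014), melanoma 3 (-0.059), melanoma 4 (-0.052) or melanoma plus lisinopril 4 (-0.17).

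The tumour response score joined the 2141 genes into a value per library. It was -0.61 ± 0.37 in control (SD, n = 4), -0.77 ± 0.075 with lisinopril (n = 3), 0.82 ± 0.56 with melanoma (n = 4) and 0.72 ± 0.37 with melanoma and lisinopril (n = 4), in log2 units. Its genes were chosen on tumour status, so its rise with tumour is no separate evidence. The drug changed it by -0.10 in tumour-bearing mice (exact two-sided permutation p = 0.771, 95% interval -1.40 to 0.67). In tumour-free mice it changed by -0.15 (exact p = 0.857, interval -1.44 to 0.41). The interaction of the score was 0.049 (exact p = 0.905). The interval in tumour-bearing mice reaches from a loss of most of the tumour effect of 1.43 to a gain, so a drug effect of that size was not excluded. Without melanoma 2 and control 2 the drug difference in tumour-bearing mice was 0.16.

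**Figure D3:**
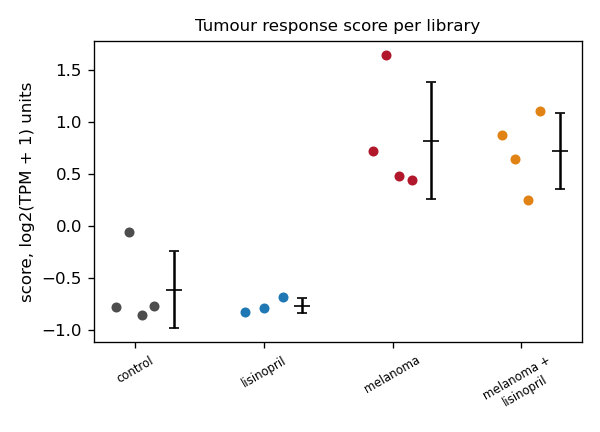
Tumour response score of each library in log2(TPM + 1) units by group, with the group mean and SD beside the points. The means with tumour were 0.82 and 0.72, those without -0.61 and -0.77.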

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

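The tests on scaling, on blood in control 2 and on the spread of atrophy genes after rescaling were chosen only after the result was seen, while the splits and the correlations of the atrophy genes were planned.

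Of 330 groups of 4 libraries, 36 held a library far from the other 3, where chance gives about 1 in 20, or 16.5. Control 2 accounted for 12 of them and melanoma 2 for 7. Only 107 genes named in the text and some values per library were looked at. Genes named because of control 2, such as Cd79a and Ms4a1, count among its flags. The genes are not independent either, so 16.5 is only a reference. In log2(TPM + 1), control 2 had the highest value of its group for Cxcr2 (1.85), Optn (5.80), Tap1 (3.76), Psmb9 (2.94), Igkc (6.34), Cd79a (4.39), Ms4a1 (2.04) and Cd3e (0.53), and the lowest for Iqcg (2.04), Lrtm1 (4.69) and Ndufs8 (7.92). Melanoma 2 had the highest value of its group for Fbxo32 (9.95), Trim63 (10.95), Ppargc1a (5.13), Rps4x (9.36) and Xbp1 (7.88), and the lowest for Trim7 (0.90) and Cox7a1 (8.31). Melanoma 4 had the highest value of its group for Myh7 (3.74), and the lowest for Cd163 (2.48). Control 1 had the highest value of its group for Col1a1 (7.61) and Ccnd1 (3.51). Melanoma plus lisinopril 3 had the highest value of its group for Fndc5 (5.79), Angptl2 (4.47) and Actc1 (5.97), and the lowest for Prg4 (2.15) and Sned1 (2.85). Control 3 had the highest value of its group for Dct (0.023), and the lowest for Atp9a (3.35). Control 4 had the lowest value of its group for Ighm (5.18). Melanoma plus lisinopril 4 had the highest value of its group for Npr3 (2.40), and the lowest for Ndufs1 (7.03). Melanoma 3 had the highest value of its group for Dct (0.028). The tumour response score was -0.061 in control 2, the highest of the controls, with the next at -0.76. Mitochondrial transcripts took 52.8% of TPM in control 3, against 41.9% in the next control. The log2 haemoglobin sum of melanoma plus lisinopril 4 was 7.37, the lowest of its group, with the next at 10.49. The tumour effect differed between the drug arms past limma's threshold for 0 genes, with 151 at an unadjusted p below 0.05.

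Of the 2141 genes called in the average tumour effect, 80.8% were higher with tumour. With TPM recomputed without the mitochondrial genome the share was 59.7% of 2154 genes, and with median-ratio rescaling 46.7% of 2368, so for the average both the smaller mitochondrial share and the scaling to a fixed sum stay open as a source of the excess. In melanoma plus lisinopril against lisinopril the share was 82.6% without the mitochondrial genome, and 76.2% when control 2 and melanoma 2 were left out too, which argues against the mitochondrial share as the whole source in that arm. With median-ratio rescaling it was 70.3% there, and 46.6% without those 2 libraries, so scaling stays open in that arm. A true rise of most transcripts with tumour also stays open, as untested, because TPM fix the sum.

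Control 2 stood apart from the other tumour-free libraries. Its haemoglobin was 5.69 times that of the next library, and it held 19.97 TPM of the B cell receptor gene Cd79a and 3.13 of Ms4a1, against at most 0.449 TPM of Cd79a in the other tumour-free libraries, while 3 of 24 genes of the lymphocyte list reached the filter in these muscles. Blood or marrow cells in the sample may account for these transcripts. This stays open and does not speak to its tumour response score of -0.061, and no biological explanation was tested, since the labels set control 2 apart in nothing. Without control 2, melanoma against control called 590 genes and the average tumour effect 3959.

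The atrophy ligases differed widely between the 8 tumour-bearing libraries, with Fbxo32 from 66.2 to 986 TPM and Trim63 from 228 to 1974. Scaling is argued against, since the smaller of their ratios of highest to median was still 4.10 after median-ratio rescaling. Levels of the atrophy list, without shared genes, followed the acute phase list over the 8 libraries (r = 0.878, exact permutation p = 6.70e-04, adjusted 0.00134 over 2 relations, rho = 0.952, exact p = 0.00114, and r = 0.934 without melanoma plus lisinopril 3 and melanoma 2). For both relations, levels were plain means of log2(TPM + 1), without subtracting the mean of all kept genes. Scaling shared by the lists was thus not removed. Melanoma 2 and melanoma plus lisinopril 4 had the largest median-ratio factors (0.30 and 0.28 log2 units). A link to the strength of the acute phase response is a candidate explanation that this correlation cannot tell from shared scaling. For the glucocorticoid list r was 0.880 (exact permutation p = 0.00352, adjusted 0.00352, rho = 0.786, exact p = 0.0279) but 0.464 without melanoma 2 and melanoma plus lisinopril 4, so that relation rests on those libraries and cannot be told apart from their being different. The libraries of the drug arms were pooled, since 4 per arm are too few for a correlation within an arm.

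Other splits of the same libraries were counted with each number of genes called. For melanoma against control 2 of 35 splits gave as many genes, so chance was not excluded (real 77, highest other 446). The split with 446 genes exchanged control 2 with melanoma 4, and since it called several times the real count it points to a structure of these libraries other than their groups. For melanoma plus lisinopril against lisinopril 1 of 35 splits, the real, gave as many (real 177, highest other 153). No share below 1 in 35 was possible, another split came close, and the 6 contrasts were not adjusted for, so chance was not excluded. For the average tumour effect 1 of 100 splits, the real, gave as many, by a wide margin that argues against chance (real 2141, highest other 1). For the other 3 contrasts the real count was 0, so every split gave at least as many and the count says nothing about chance: 35 of 35 for lisinopril against control (highest other 2), 35 of 35 for melanoma plus lisinopril against melanoma (highest other 6) and 100 of 100 for the interaction (highest other 1).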

How the results depend on the processing

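The settings without the mitochondrial genome and without control 2 and melanoma 2, with or without median-ratio rescaling, were chosen only after the result was seen. Over all results and settings 6972 values kept their direction and side of the threshold, 1148 kept the direction only, 8 gained the threshold, 63 counts or values moved and 108 turned, in sign or in the direction of the list test. Of 115 named genes called in the average tumour effect, 99 stayed past the threshold with median-ratio rescaling, 104 with quantile normalization, 91 with no filter and 107 without the mitochondrial genome. Lisinopril against control, melanoma plus lisinopril against melanoma and the interaction called 0 genes by limma under each setting run, with 461, 189 and 151 at an unadjusted p below 0.05 in the reported fit. The deposited TPM do not give the depth, so what depth limits is unknown. Unless stated, the cause was not tested.

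Genes called for melanoma against control came to 40 with no filter, 30 with the stricter filter, 163 with median-ratio rescaling, 359 with quantile normalization, 1710 with sample quality weights, 137 without the mitochondrial genome, 257 without control 2 and melanoma 2, 594 with rescaling as well, and 5 with only the 2 groups compared. For melanoma plus lisinopril against lisinopril they came to 14 with no filter, 2303 with weights, 1914 without the same 2 libraries, 1911 with rescaling as well, and 876 with only the 2 groups compared. For the average tumour effect they came to 1337 with no filter, 4660 with weights, 3676 without the 2 libraries and 3648 with rescaling as well. Lists called came to 12 for melanoma against control without the 2 libraries and with rescaling, 8 for melanoma plus lisinopril against melanoma with quantile normalization, and 11 for melanoma plus lisinopril against lisinopril with median-ratio rescaling. With an estimated correlation they came to 1 for melanoma against control, 1 for melanoma plus lisinopril against melanoma, 1 for the interaction, and 0 for the other 3 contrasts.

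The labels give replicate numbers shared between groups, so the number was tried as a block. Of pairs of libraries with the same number, 9 of 21 had a residual correlation above 0.1 (median 0.0833), against 16 of 63 pairs with different numbers (median -0.0354). Not every pair of the same number was above it, and 4 of 15 libraries were closest to their own number. With the replicate block 120 genes were called for melanoma against control and 356 for melanoma plus lisinopril against lisinopril.

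Sign changes of melanoma plus lisinopril against melanoma, in log2 units, were Fbxo32 0.24, Pdk4 0.34, Fkbp5 0.46, Lcn2 0.33 and Serpina3n 0.25 without control 2 and melanoma 2, Fbxo32 0.25, Pdk4 0.35, Fkbp5 0.47, Lcn2 0.35 and Serpina3n 0.27 with rescaling as well, Pdk4 0.058 and Fkbp5 0.016 with median-ratio rescaling, Trim63 -0.030 with quantile normalization, and Mstn -0.066, Fkbp5 0.39 and Lcn2 0.21 with weights. The score difference of that comparison was 0.16 and 0.11 in the first of these settings and the second. List medians or the directions of their tests turned without the 2 libraries, to proteasome subunits -0.037 and erythrocytes 0.29 in melanoma against control, and interferon-stimulated genes 0.011 in lisinopril against control, and fast fibre sarcomere -0.033, glycolysis and glycogen -0.040, cytoplasmic ribosomal proteins 0.038 and erythrocytes -0.13 in melanoma plus lisinopril against melanoma, and proteasome subunits 0.12 and interferon-stimulated genes -0.096 in the interaction. With rescaling as well they became proteasome subunits -0.066 and erythrocytes 0.26 in melanoma against control, and interferon-stimulated genes -0.026 in lisinopril against control, and fast fibre sarcomere -0.031, glycolysis and glycogen -0.038, cytoplasmic ribosomal proteins 0.040 and erythrocytes -0.10 in melanoma plus lisinopril against melanoma, and proteasome subunits 0.10 and interferon-stimulated genes -0.089 in the interaction. Quantile normalization gave proteasome subunits -0.044 and mitochondrially encoded mRNAs -0.050 in lisinopril against control, and mitochondrially encoded mRNAs 0.036 and glycolysis and glycogen 0.014 in the interaction. No filter gave proteasome subunits -0.019 in lisinopril against control, and extracellular matrix 0.082 in melanoma plus lisinopril against lisinopril, and the replicate block neutrophils 0.028 in the interaction. The stricter filter, which tests fewer genes, gave tendon and cartilage 0.53 in melanoma plus lisinopril against lisinopril.

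Leaving out each library gave 17 to 590 genes for melanoma against control, 5 to 681 for melanoma plus lisinopril against lisinopril and 743 to 3959 for the average tumour effect. The score difference with the drug in tumour-bearing mice ran from -0.28 to 0.18 and the interaction of the score from -0.15 to 0.36. Log2 changes of melanoma plus lisinopril against melanoma ran from -0.93 to 0.25 for Fbxo32, -0.39 to 0.65 for Trim63, -0.17 to 0.57 for Foxo1, -0.32 to 0.57 for Cdkn1a, -0.33 to 0.65 for Mt2, -0.14 to 0.38 for Agt, -0.044 to 0.47 for Mstn, -0.58 to 0.34 for Pdk4, -0.38 to 0.46 for Fkbp5, -1.10 to 0.47 for Lcn2, -1.39 to 0.25 for Serpina3n, -1.15 to 0.12 for Col1a1 and -1.32 to 0.16 for Col3a1. In melanoma against control, list medians ran from -0.58 to 0.015 for slow fibre sarcomere. In lisinopril against control, list medians ran from -0.11 to 0.047 for fatty acid oxidation and PPAR targets, -0.90 to 0.011 for interferon-stimulated genes, -0.028 to 0.29 for immediate early genes and -0.42 to 1.47 for erythrocytes. In melanoma plus lisinopril against melanoma, list medians ran from -0.033 to 0.43 for fast fibre sarcomere, -0.051 to 0.63 for slow fibre sarcomere, 0.0067 to 0.19 for oxidative phosphorylation complexes II to V, -0.040 to 0.35 for glycolysis and glycogen, -0.23 to 0.038 for cytoplasmic ribosomal proteins and -0.13 to 1.46 for erythrocytes. In melanoma plus lisinopril against lisinopril, list medians ran from -0.39 to 0.15 for extracellular matrix. In the interaction, list medians ran from -0.22 to 0.072 for proteasome subunits, -0.24 to 0.0044 for oxidative phosphorylation complex I, -0.36 to 0.016 for mitochondrially encoded mRNAs, -0.57 to 0.0012 for glycolysis and glycogen and -0.014 to 0.93 for interferon-stimulated genes. The analysis of read counts was not run because the table holds TPM.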

Other observations

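The lymphocyte and melanocyte tests were planned, and the permutation test of lists was chosen only after the data were seen. Several clock genes changed in the average tumour effect. The output regulator Dbp (-1.99 ± 0.52) fell, while Nfil3 (1.95 ± 0.39), its repressing counterpart, and the core clock gene Per2 (0.65 ± 0.19) rose. As a list the circadian clock had 4 of 18 members higher and 1 lower (median 0.094 relative to all genes, adjusted p = 0.928 by limma's camera). Among secreted factors of muscle, osteocrin, Ostn (-2.47 ± 0.57), and interleukin-15, Il15 (-0.75 ± 0.16), fell. Their list, the TGF-beta family and myokines, was not called by camera and did not pass the exact permutation test (p = 0.108, adjusted 0.210). Macrophage markers divided between Cd163 (1.92 ± 0.26), F13a1 (1.97 ± 0.32) and the mannose receptor Mrc1 (1.02 ± 0.25), which rose, and 3 members that fell (median 0.41, adjusted p = 0.971 by limma's camera). Desmin, Des (1.07 ± 0.19), an intermediate filament of muscle cells, rose. Of insulin, IGF and mTOR signalling genes 8 of 25 rose, with the regulatory subunit Pik3r1 (1.53) and the receptor Igf1r (1.21) among them. That list did not pass by camera (adjusted p = 0.133) but passed the exact permutation test (p = 9.32e-04, adjusted 0.00546), with the direction in 8 of 8 tumour-bearing libraries.

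The renin-angiotensin and kinin list, on which the drug acts, had 2 of 19 members higher with tumour (median 0.10, adjusted p = 0.727 by limma's camera). With lisinopril in tumour-free mice the list was lower by camera (median -0.12 relative to all genes, adjusted p = 0.0214, and adjusted p = 0.643 with an estimated correlation; unadjusted median -0.31), with 0 members past the threshold over all genes and 0 adjusted over the list alone, and the call ended without control 1 (-0.097) or lisinopril 1 (-0.15). In the average tumour effect Ace was past the threshold (log2 fold change 1.80 ± 0.30, adjusted p = 0.00282), and was above every tumour-free library in 6 of 8 tumour-bearing libraries, while Agt (log2 fold change 0.65 ± 0.28, adjusted p = 0.105) and Agtr1a (log2 fold change 0.24 ± 0.17, adjusted p = 0.298) were not past it. Ace lies on chromosome 11 at 105967945 to 105989964 of mm10.

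A xenograft is usually grown in hosts without mature lymphocytes, whereas the labels give C57BL/6J. In 15 of 15 libraries the larger of Ighm and Igkc was at least 1 TPM, which argues against hosts that make no immunoglobulin transcripts. Ighm ran from 1.83 to 167 TPM, and Cd3e, of the T cell receptor complex, reached at most 0.439 TPM. Gene-level TPM do not show whether the receptor genes were rearranged, and this was not tested.

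The melanocyte genes Pmel, Mlana, Tyr, Tyrp1 and Dct were looked at for tumour transcripts in the muscle. The largest excess in tumour-bearing over tumour-free libraries was 0.00784 TPM, for Dct, which argues against mouse melanoma cells with these transcripts in the tissue. The labels call the tumour a xenograft without naming its species, and values computed against the mouse genome alone cannot show whether transcripts of a human tumour were present. The highest value in any library was 0.327 TPM, of Pmel. As a list, melanocyte and melanoma genes had 3 kept members (median -0.51, adjusted p = 0.217 by limma's camera; exact permutation p = 0.00404, adjusted 0.0184, below the tumour-free mean in 8 of 8 tumour-bearing libraries). None of the genes looked at above is among the kept members, since all stayed below the filter, so the list result does not speak to them.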
